A study of Mus musculus with 11 samples.

How the data were processed

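Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 cuts and tags open DNA, in 11 libraries of naive CD4 T cells from spleen and lymph nodes of 3 mice. The mice carry a transgene that makes green fluorescent protein from the Nr4a1 (Nur77) promoter, which reports signalling through the T cell receptor, and a red reporter of Foxp3. Each library came from 10000 cells and a tagmentation of 1 h at 37 °C. Cells negative for the Foxp3 reporter and low for CD44 were sorted into population A (reporter low, Ly6C positive, n = 2), B (reporter intermediate, Ly6C positive, n = 3), C (reporter intermediate, Ly6C negative, n = 3) and D (reporter high, Ly6C negative, n = 3). The number in each library's name gives its mouse, and mouse 2 has no library of population A.

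The deposited table lists 45508 peaks on the mm10 build, each with its position, an annotation, the nearest gene assigned by the authors and 1 value per library. The deposited values are in RPM, reads scaled to a common total, and are called rppm per the file headers. The denominator is not stated. The submitters' processing notes name Bowtie and MACS2 without versions or roles, and the read filters, the merging of peaks and the pooling of libraries for peak calling are not stated. All 45508 peaks reached 1 rppm in at least 3 libraries. Every column was a set of whole multiples of 1 step (100% of values within 6e-04 rppm), so the value of 1 read, the denominator and whole read numbers were recovered for all 11 libraries. The denominators ran from 2597176 to 36859229 reads, of which 92.5% to 94.7% fell in the listed peaks. Such shares point to a total of reads in all peaks of a longer list rather than of all mapped reads, which is not documented. A peak at 10 rppm therefore rested on 26 reads in the shallowest library and on 369 in the deepest. Reads carry no molecular identifiers and the read filters are not stated, so these numbers may include copies of the same fragment. They are an upper limit on independent fragments and do not describe spread between mice. Entrez identifiers of 45447 peaks (99.9%) matched the mouse reference annotation of the same assembly, and 15 peaks had no gene.

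The main analysis used limma 3.58.1 in R 4.3.3 on log2(rppm + 1), with 1 mean per population, all 11 libraries in 1 model, a variance trend with peak level and no term for the mouse. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over 45508 peaks within each contrast, with a threshold of 0.05. "Called" below means past that threshold. A log2 change refers to rppm + 1, so it understates ratios at peaks with low values. The contrasts were D against A, the 3 neighbouring steps (B against A, C against B, D against C), C against A, D against B, any difference among populations, and the difference between the D minus C and B minus A steps. These contrasts, the model, the gene lists, the rule for named peaks and most alternatives were fixed before the data were examined. Promoter shares were compared by two-sided Fisher's exact test.

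The rule for named peaks took the 10 higher and 10 lower peaks with the largest change in D against A, and the 5 higher and 5 lower in each neighbouring step. It asked for a call, a mean of at least 5 rppm in the higher population and no overlap between the libraries, with 1 peak per gene and genes with a proper symbol only. It added sort and gate genes, among them Nr4a1, Ly6c1, Ly6c2, Cd44, Foxp3, Cd4 and Cd8a, and up to 4 genes with the smallest p from each list. The 14 lists covered genes induced by T cell receptor signalling, negative regulators of activation, naive homing and quiescence, the type I interferon response, the Ly6 cluster, effector and memory cells, follicular helper cells, regulatory T cells, AP-1, NFAT and NF-kB factors, thymocytes and recent thymic emigrants, core T cell identity, B cells, myeloid and dendritic cells, and CD8 T and NK cells. Each was tested by camera (limma) with a preset correlation of 0.01, again with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over the 14 lists. Peaks near 1 gene are not independent measurements. A peak enters a list by its nearest gene, which need not be the gene it regulates.

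Libraries of the same mouse were compared through their deviations from the population means. The 15 pairs from 1 mouse correlated at 0.18 to 0.56 (median 0.36), and the 30 pairs from different mice at -0.43 to 0.2 (median -0.21). Deviations cancel within a population by construction. This pushes pairs from different mice toward negative values when pairs from 1 mouse are positive, so the negative values are not a separate observation. Counts of called peaks with the mouse as a block are therefore given beside those without it. Alternatives fixed in advance were other pseudocounts (0.25 and 5), a minimum mean of 5 rppm, median-of-ratios scaling, quantile normalization, robust moderation, the mouse block, a correction for peak width, the block with that correction, only the populations compared, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Chosen after seeing the data were libraries thinned to equal reads and the omission of mouse 1 or of mouse 3. Omitting either mouse left population A with 1 library, assumed to vary like the other groups.

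The model was tested on simulated data in which 200 of 45508 peaks, drawn from those above a minimum mean level, were changed. It recovered 57%, 53%, 69% and 77% of 2-fold changes in D against A, B against A, C against B and D against C, and 9%, 15%, 18% and 23% of 1.5-fold changes. Between 2.91% and 4.23% of its calls were false. A list shifted 1.3-fold was called by camera, and 0 of 10 lists sharing no peak with it were. Libraries were simulated without a mouse effect and without correlation among peaks. The share of false calls therefore does not test the omission of the mouse, nor does the list check test the preset correlation. The genome sequence was not available, so the planned motif shares and correction for GC content were not run, and peak width took the place of GC content.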

Results

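Open chromatin was measured by ATAC-seq in naive CD4 T cells sorted into 4 populations by a green reporter of Nr4a1 (Nur77), a gene switched on by T cell receptor signalling, and by the surface protein Ly6C. Population A (reporter low, Ly6C positive) had 2 libraries, from mice 1 and 3. Populations B (reporter intermediate, Ly6C positive), C (reporter intermediate, Ly6C negative) and D (reporter high, Ly6C negative) had 3 libraries each, from mice 1, 2 and 3. Values are RPM (rppm) at 45508 peaks, of which 26.8% lie within 1 kb of an annotated transcription start site. The totals by which reads were scaled, whose definition is not stated, were 9194084 and 9933354 in A, 8736371 to 25061501 in B, 5095885 to 35244031 in C and 2597176 to 36859229 in D. Mouse 3 gave the deepest library of every population, and population D replicate 1 was the shallowest library. Values are given as mean ± SD with n = 2 for A and n = 3 for B, C and D, and log2 changes as the limma estimate with its standard error (SE).

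The comparison of D with A sets the strongest reporter signal against the weakest, and Ly6C negative against positive cells. It cannot tell the effects of these markers apart. Among the peaks that rose most was 1 in intron 6 of Ikzf2, which encodes the transcription factor Helios (mm10, chromosome 1, 69544126 to 69544705), with 0.105 ± 0.00566 rppm in A and 11.7 ± 3.92 in D. A peak in intron 3 of Ctla4, an inhibitory receptor (chromosome 1, 60913269 to 60913747), rose from 2.7 ± 0.74 to 23 ± 0.727 rppm. A peak 28.8 kb from the start of Ndrg1, a gene linked to T cell anergy (chromosome 15, 66998045 to 66998931), rose from 0.729 ± 0.107 to 16.1 ± 1.56 rppm. A peak 14.9 kb from the start of Ly6c1, which encodes part of the sort marker Ly6C (chromosome 15, 75033381 to 75034218), fell from 20.3 ± 0.962 to 5.46 ± 0.482 rppm. The plot of accessibility per library shows these peaks mouse by mouse.

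**Figure D1:**
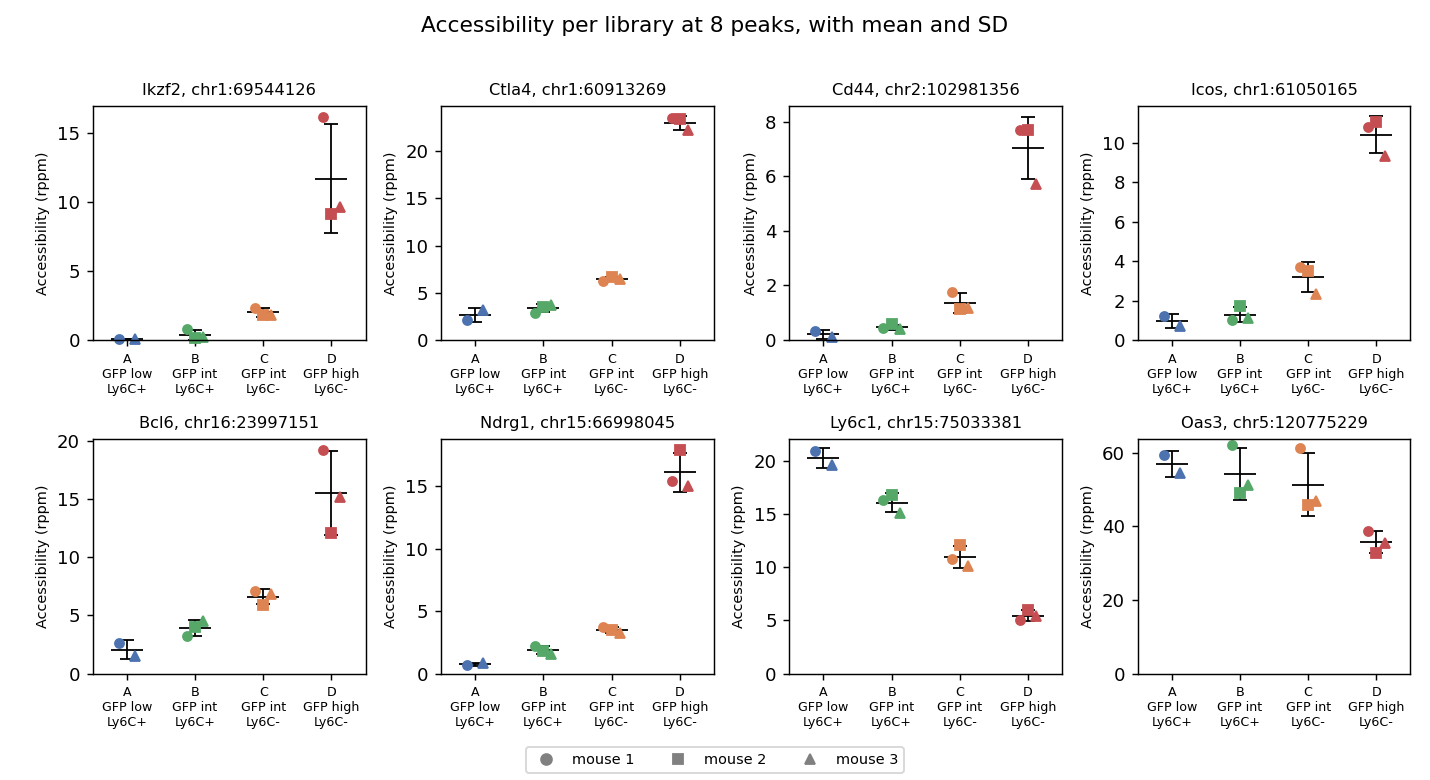
Accessibility (rppm, linear axis from 0) of each library at 8 peaks, by population; symbols mark the mouse, and bars the mean and SD (n = 2 for A, n = 3 for B, C and D). At the Ctla4 peak the mean goes from 2.7 in A to 23 in D, and at the Ly6c1 peak from 20.3 to 5.46.

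In all, 5658 of 45508 peaks differed between D and A at a limma adjusted p below 0.05, of which 3957 (69.9%) were higher in D and 1701 lower. The higher peaks were assigned to 2538 genes, with a median log2 change of 1.01, and 2030 of them changed at least 2-fold. The lower peaks were assigned to 1173 genes, with a median of -0.71, and 273 changed at least 2-fold. With the mouse as a block, 9668 peaks were called, 5667 higher and 4001 lower. The count was 3115 without population A replicate 1, which left A with 1 library assumed to vary like the other groups, and 2930 without population A replicate 3. It was 3763 with only A and D in the model, 3078 among peaks with a mean of at least 5 rppm, and 2742 with all libraries thinned to equal reads. Without mouse 3, which gave the deepest libraries and 1 of the 2 libraries of A, it fell further, and each peak still called was also called with all mice.

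**Figure D2:**
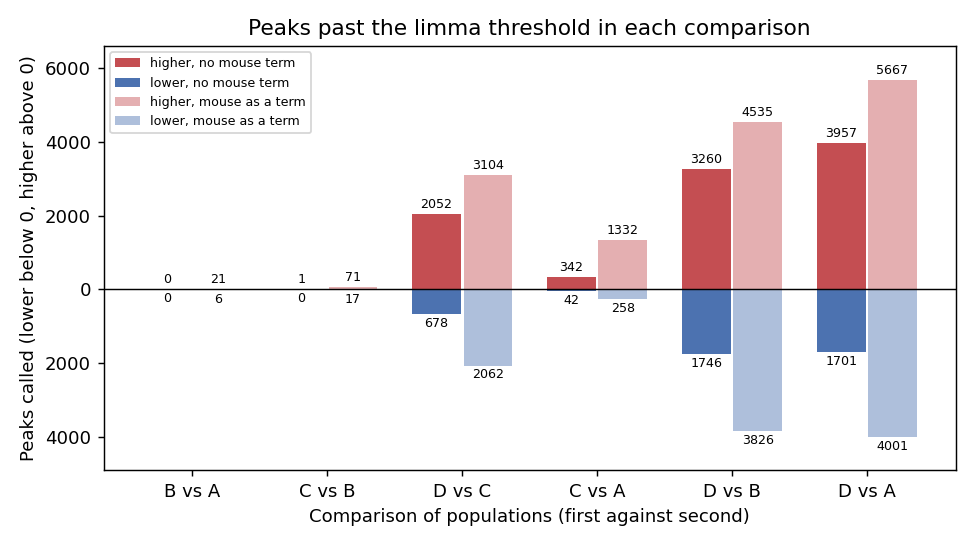
Number of peaks called by limma in each comparison (higher above 0, lower below 0), without a mouse term (dark) and with the mouse as a block (light). D against A gives 3957 higher and 1701 lower peaks without the block, while B against A gives 0.

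The 10 higher peaks taken by the naming rule lay near Ergic1, Swap70, Ppp2r5c, Ankdd1b, Sik3, Bckdhb, Stk39, Ikzf2, Myo10 and Ndrg1, with log2 changes from 4.22 down to 3.30. The largest was 10.2 kb from Ergic1 (chromosome 17, 26550925 to 26551693), at 0.206 ± 0.136 rppm in A and 21.8 ± 5.9 in D (log2 4.22, SE 0.21, limma adjusted p = 1.93e-07). The peak in intron 2 of Swap70 (chromosome 7, 110253764 to 110254824) rose from 0.834 ± 0.103 to 26.4 ± 5.52 rppm. The Ikzf2 peak had a log2 change of 3.48 (SE 0.25, limma adjusted p = 1.65e-06) and the Ndrg1 peak 3.30 (SE 0.17, limma adjusted p = 1.93e-07). The 10 lower peaks lay near Rab3gap1, Mocs1, Neto2, Trps1, Gramd3, Myo6, Sall3, Ly6c1, Slc9a9 and Elovl5, with log2 changes from -2.08 to -1.63. The peak in intron 1 of Gramd3 (chromosome 18, 56440745 to 56441396) fell from 19.1 ± 3.19 to 4.69 ± 0.508 rppm, and the Ly6c1 peak had a log2 change of -1.72 (SE 0.14, limma adjusted p = 2.79e-06). By the rule, no library of A overlapped any of D at these 20 peaks. With thinned libraries limma no longer called Slc9a9 (adjusted p = 0.0973), and without mouse 3 it no longer called Trps1 (0.0555).

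Genes of regulatory and follicular helper T cells gained accessible peaks in D. Of 92 peaks of the regulatory T cell list, 27 were higher in D than in A and 4 lower (33 and 4 adjusted over the list alone). Of its 18 genes, 8 had only higher peaks, 2 had peaks in both directions and 8 had no called peak. Besides Ctla4 and Ikzf2, the promoter of Itgb8, an integrin chain that activates TGF-beta, rose from 0.155 ± 0.0651 to 7.3 ± 0.945 rppm (log2 2.84), and a peak near Tnfrsf9, the costimulatory receptor 4-1BB, rose from 1.26 ± 0.0686 to 6.86 ± 0.813 rppm. The cells were sorted negative for the Foxp3 reporter, and the 1 peak of Foxp3, the defining factor of regulatory T cells, was not called (3.74 ± 0.87 and 5 ± 1 rppm, log2 0.34, limma adjusted p = 0.387). Of 108 peaks of the follicular helper list, 31 were higher and 0 lower (38 and 3 adjusted over the list alone), and 11 of its 14 genes with peaks had only higher ones. Peaks near Bcl6, the lineage's master regulator (2.06 ± 0.778 to 15.5 ± 3.6 rppm), Icos, a costimulatory receptor (0.95 ± 0.347 to 10.4 ± 0.94 rppm), and Il21, its main cytokine (0.993 ± 0.0198 to 7.2 ± 0.317 rppm), rose. Under the mouse block, 37 peaks of the regulatory list were higher and 4 lower, and 39 and 3 of the follicular helper list. Both lists were called higher by camera (limma adjusted p = 2.82e-09 for each, and adjusted p = 0.00536 for each with an estimated correlation). Of the regulatory T cell genes 6, and of the follicular helper genes 5, also stand in another list.

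Negative regulators of T cell activation also rose. Of their 367 peaks, 82 were higher and 9 lower (95 and 15 adjusted over the list alone, 111 and 23 with the mouse block), and 23 of 38 genes had only higher peaks, 3 only lower ones, 3 both and 9 none. After Ndrg1 and Ctla4, the leading genes were Rasa2, which restrains Ras (0.21 ± 0.012 to 6.41 ± 0.484 rppm, log2 2.61), and Cd200, whose product binds an inhibitory receptor (1.95 ± 0.624 to 17.2 ± 3.21 rppm, log2 2.62). The list was called higher by camera (limma adjusted p = 8.12e-06, and adjusted p = 0.00899 with an estimated correlation). Genes induced by T cell receptor signalling had 35 higher and 10 lower peaks of 179 (38 and 10 adjusted over the list alone, 43 and 14 with the mouse block). They include the promoter of Tnfrsf4, the costimulatory receptor OX40 (4.73 ± 0.998 to 15.2 ± 1.36 rppm), and a peak near Tagap, a T cell GTPase activator (1.19 ± 0.453 to 6.16 ± 1.07 rppm). This list was called higher by camera (limma adjusted p = 0.00748), a call lost with an estimated correlation (adjusted p = 0.126). Nr4a1 itself had 8 peaks, of which 3 were higher in D and 0 lower (5 higher with the mouse block). The one with the smallest p (chromosome 15, 101256068 to 101256384) rose from 4.09 ± 1.33 to 10.5 ± 0.433 rppm (log2 1.20, limma adjusted p = 0.00144). Reads from the reporter transgene would map to the same place where it carries Nr4a1 sequence.

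Effector, memory and thymocyte genes had called peaks in both directions. Of 145 peaks of the effector and memory list, 23 were higher and 6 lower, with rises near Ifng, the cytokine interferon gamma (1.2 ± 0.156 to 12.3 ± 0.987 rppm), Cd44, an adhesion receptor of activated cells (0.214 ± 0.159 to 7.04 ± 1.14 rppm) and S100a6 (log2 2.03). Of the 15 peaks of Cd44, a gate marker, 4 were higher and 1 lower. Of 129 peaks of the thymocyte and recent emigrant list, 26 were higher and 6 lower, with rises near Tox (log2 1.93), Bcl11b (log2 1.61), Id3 (log2 1.91) and Rag2 (log2 2.05). The counts with the mouse block were 28 higher and 14 lower for the first list and 35 and 10 for the second. Both lists were called higher by camera (limma adjusted p = 0.0454 and 0.0107), and both calls were lost with an estimated correlation (adjusted p = 0.236 and adjusted p = 0.146).

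Some peaks of the Ly6 cluster, and a few of interferon-response genes, were lower in D. Of 41 Ly6 peaks, 12 were lower and 0 higher (17 lower adjusted over the list alone, 15 with the mouse block), near Ly6c1, Ly6a and Ly6e, and 5 of its 8 genes with peaks had none called. The promoter of Ly6a, which encodes Sca-1, went from 7.72 ± 1.23 to 3.42 ± 0.781 rppm (log2 -0.99). Ly6c2, the other Ly6C gene, had 0 called peaks of 5 by limma, and its peak with the smallest p stood at 14.1 ± 0.4 and 10.9 ± 0.203 rppm (limma adjusted p = 0.101). Of 76 peaks of type I interferon genes, 5 were lower and 0 higher (2 lower adjusted over the list alone, 11 with the mouse block), and 24 of 27 genes had no called peak. The lower ones were at Oas3, Oasl2 and Ifit3, with Oas3, an antiviral enzyme, falling from 57 ± 3.49 to 35.7 ± 3.02 rppm (log2 -0.66). With only 1 library of A left, some calls were lost at changes of similar size and larger SE. Without population A replicate 1 limma no longer called Oas3 (log2 -0.60, SE 0.19 in place of 0.14, adjusted p = 0.0913), Ifit3 (log2 -0.85 in place of -0.82, SE 0.31 in place of 0.24, 0.162), Ly6a (log2 -0.84, SE 0.26 in place of 0.20, 0.0812) or the Ly6e peak with 28.2 rppm in A (log2 -0.50 in place of -0.51, SE 0.15 in place of 0.11, 0.0759). Without A replicate 3 it did not call Oasl2 (log2 -0.81 in place of -0.97, SE 0.28 in place of 0.22, 0.135), Ifit3 (log2 -0.80, SE 0.31, 0.198) or Ly6e (log2 -0.52, SE 0.15, 0.0689). Ifit3 was also lost without D replicate 1 (0.0732) or D replicate 2 (0.0621), without mouse 1 (0.14), by edgeR (0.0545) and by DESeq2 (0.057). With only A and D in the model Oasl2 (0.0527), Ifit3 (0.0587) and Ly6e (0.0657) were lost, and with thinned libraries too (0.464, 0.261 and 0.648). Without mouse 3 limma called none of Oas3 (0.22), Oasl2 (0.235), Ifit3 (0.19), Ly6a (0.0763) and Ly6e (0.368). Camera called both lists lower (limma adjusted p = 6.16e-06 for Ly6 and 0.00748 for interferon), and both calls were lost with an estimated correlation (adjusted p = 0.146 for each). On promoter peaks alone the interferon call was lost too (camera in limma, adjusted p = 0.0731).

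Peaks of 6 lists changed without a call for the list. Naive homing and quiescence genes had 35 higher and 28 lower peaks of 472 (camera in limma, adjusted p = 0.411), and 48 higher and 58 lower with the mouse block, where the balance turned. Of the 20 genes, 0 had only higher peaks, 3 only lower ones, 9 both and 8 none. Bach2, a repressor of effector programs, was among those with both. Single peaks rose at Foxp1 (log2 2.89), Klf3 (log2 2.39) and Btg1 (log2 0.89, not called by limma without mouse 3). At Il7r, 8 of 19 peaks were lower and 0 higher. Core T cell identity genes had 32 higher and 12 lower peaks of 275 (adjusted p = 0.165), and 41 and 22 with the block. Of the 19 identity genes with peaks, 4 had only higher ones, 4 only lower ones, 4 both and 7 none called. Single peaks rose at Runx1 (log2 1.72), Fyn (log2 2.76) and Ets1 (log2 2.40). Genes of AP-1, NFAT and NF-kB factors had 13 higher and 2 lower of 123, and 22 and 10 with the block, led by Nfkb1 (log2 1.91), with a median log2 change of -0.02 and a mean of 0.07. Their list was not called (adjusted p = 0.697, direction higher), but on promoter peaks alone it was called lower (adjusted p = 0.0347).

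The lists of B cells, of myeloid and dendritic cells, and of CD8 T and NK cells were not called on all their peaks. The list of regulatory T cells, which the Foxp3 reporter gate should remove, was called higher, as given above. The B cell list had 3 higher peaks of 24, at H2-Aa (log2 1.5), Btk (log2 0.68) and H2-Eb1 (log2 0.55), and was not called (camera in limma, adjusted p = 0.411), although it was called higher on promoter peaks alone (adjusted p = 0.017). Of its 18 genes, 9 had no listed peak, Ms4a1 and Pax5 among them. The myeloid and dendritic list had 6 higher and 4 lower of 37 (adjusted p = 0.708, median -0.07, mean 0.02), with Itgax at log2 -0.98. The CD8 T and NK list had 4 higher and 5 lower of 45 (adjusted p = 0.17), with Runx3 at log2 2.06 and Prf1, which encodes perforin, at log2 -0.96. The counts with the mouse block were 3 higher and 2 lower for B cell, 6 and 7 for myeloid and 5 and 11 for CD8 T and NK genes. Without population A replicate 1 the limma call was lost at Btk (log2 0.58, adjusted p = 0.163), H2-Eb1 (log2 0.66, 0.0564) and Itgax (log2 -0.86, 0.0847), and without A replicate 3 at H2-Eb1 (log2 0.45, 0.221). H2-Eb1 was also lost with only A and D (0.0836), by DESeq2 (0.061) and with thinned libraries (0.125), and Btk without mouse 1 (0.0692) and with thinned libraries (0.177). Without mouse 3 the limma calls at H2-Aa (0.0566), Btk (0.166), H2-Eb1 (0.457), Itgax (0.132), Runx3 (0.0563), Cd8a (0.653) and Cd4 (0.523) were lost. The 1 peak of Cd8a stood at 4.89 ± 0.933 rppm in A and 8.39 ± 1.01 in D (log2 0.68, SE 0.18, limma adjusted p = 0.0237), a call lost without population A replicate 3 (log2 0.51, SE 0.23, 0.271), without D replicate 3 (0.0642), with only A and D (0.0746) and with thinned libraries (0.483). Of 3 peaks of Cd4, 1 stood at 7.71 ± 0.909 and 4.74 ± 0.449 rppm (log2 -0.60, SE 0.18, limma adjusted p = 0.0442). Its call was lost without population A replicate 1 (log2 -0.71, SE 0.24, 0.112), A replicate 3 (log2 -0.49, SE 0.24, 0.329), B replicate 2 (0.061), B replicate 3 (0.0578), C replicate 2 (0.0591), D replicate 1 (0.0597), D replicate 2 (0.106) or D replicate 3 (0.0555). It was also lost among peaks of at least 5 rppm (0.056), with only A and D (0.0945), by DESeq2 (0.0818) and with thinned libraries (0.343).

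**Figure D3:**
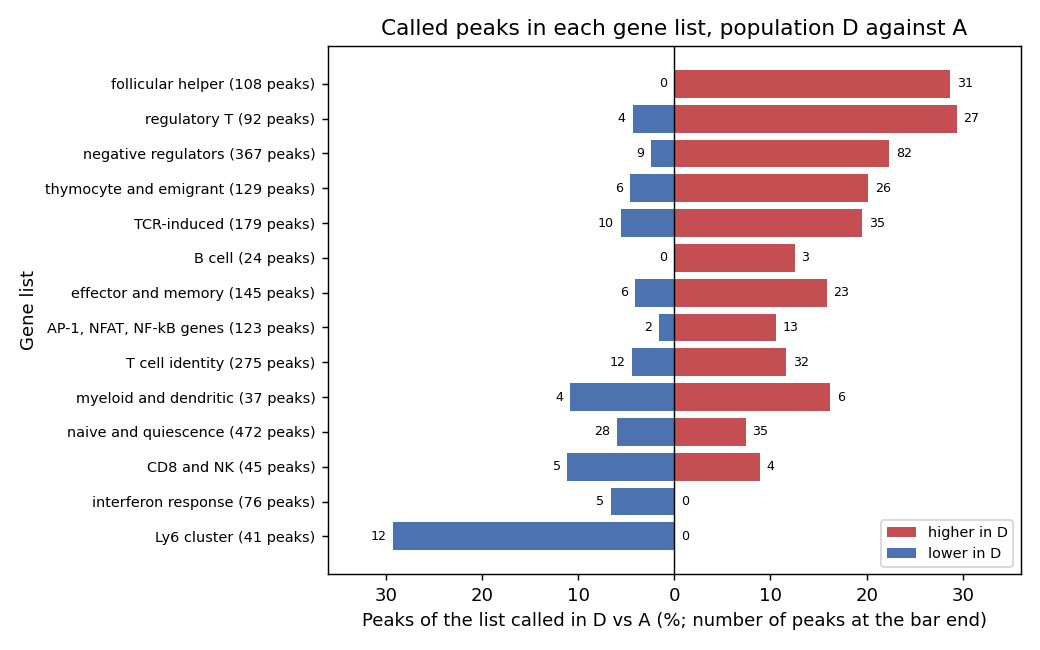
Share (%) of each gene list's peaks called higher (right) or lower (left) in D against A, with the number of peaks at each bar end. The follicular helper list has 31 higher and 0 lower of 108, and the Ly6 cluster 12 lower and 0 higher of 41.

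Changed peaks lay away from promoters. Of the higher peaks 334 (8.44%), and of the lower peaks 110 (6.47%), were within 1 kb of a start site, against 29.5% of 39850 uncalled peaks. The odds ratios were 0.22 (95% confidence interval 0.196 to 0.247, Fisher's exact p = 2.72e-215) and 0.165 (0.135 to 0.201, p = 5.88e-121), and neighbouring peaks are not independent. Introns held 47.8% of higher and 48.3% of lower peaks, against 40.2% of uncalled ones, and intergenic sequence 41.3% and 41.9% against 31%. With the mouse block, 24.5% of the lower peaks were at promoters, an odds ratio of 0.764.

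The step from C to D raises the reporter among Ly6C negative cells. Peaks of the same genes rose: Ctla4 (6.49 ± 0.202 to 23 ± 0.727 rppm, log2 1.68), Ikzf2 (2 ± 0.311 to 11.7 ± 3.92 rppm, log2 2.04), Icos (3.18 ± 0.751 to 10.4 ± 0.94 rppm, log2 1.46) and Ifng (3.65 ± 0.34 to 12.3 ± 0.987 rppm, log2 1.52). The named higher peaks were near Scyl2, Stk39, Ergic1, Sik3 and Akr1d1, led by intron 2 of Scyl2 (chromosome 10, 89677829 to 89678555; 0.567 ± 0.329 to 11.6 ± 1.31 rppm, log2 3.02, SE 0.18, limma adjusted p = 2.94e-06). The named lower ones included peaks near Syt6, Zc3h12a, Neto2 and Hnrnpd, with log2 changes from -1.35 to -1.08. The peak near Zc3h12a, which encodes the RNase Regnase-1, fell from 6.31 ± 0.655 to 2.42 ± 1.01 rppm. An intergenic peak near Bach2 fell from 73.8 ± 5.9 to 46.1 ± 1.74 rppm (log2 -0.67), and the Ly6c1 peak from 11 ± 1.03 to 5.46 ± 0.482 rppm (log2 -0.89), although both populations were sorted Ly6C negative. With thinned libraries limma no longer called Zc3h12a (adjusted p = 0.155), Hnrnpd (0.141) or Ly6c1 (0.0835), and with only C and D in the model not Hnrnpd (0.0524). Without mouse 3 it no longer called Neto2 (0.068), Hnrnpd (0.193), Bach2 (0.0607) or Ly6c1 (0.0754).

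limma called 2730 peaks between D and C, 2052 higher and 678 lower, and 5166 with the mouse block (3104 and 2062). The median log2 change was 0.91 for higher and -0.65 for lower peaks. The count was 1796 without population C replicate 2, 1144 among peaks of at least 5 rppm, 1426 with only C and D in the model, 945 with libraries thinned to equal reads and 404 without mouse 3.

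By list, follicular helper genes had 19 higher and 0 lower peaks and regulatory T cell genes 18 and 1 in D against C (26 and 2, and 23 and 3, adjusted over the list alone; 25 and 2, and 21 and 3, with the mouse block). Both were called higher by camera (limma adjusted p = 2.38e-06 for each, and adjusted p = 0.0169 for each with an estimated correlation). Negative regulators had 48 higher and 4 lower peaks, 56 and 10 adjusted over the list alone and 63 and 17 with the block (limma adjusted p = 0.00237, and adjusted p = 0.0438 with an estimated correlation). With the mouse block and an estimated correlation, follicular helper genes (adjusted p = 0.0831) and negative regulators (adjusted p = 0.125) were no longer called. Camera also called receptor-induced genes (20 higher, 4 lower, limma adjusted p = 0.0312), thymocyte genes (17 and 2, 0.0316) and effector genes (19 and 4, 0.0421) higher, and interferon (3 lower, 0.00767) and Ly6 genes (2 lower, 0.00802) lower. Those calls were lost with an estimated correlation (adjusted p = 0.191, 0.258, 0.261, 0.191 and 0.374 in that order). These lists had 26 higher and 8 lower, 22 and 4, 23 and 9, 0 and 0, and 0 and 2 peaks adjusted over the list alone, and 28 and 9, 22 and 4, 25 and 10, 1 and 8, and 0 and 2 with the mouse block. The 3 interferon peaks, at Oas3, Oasl2 and Ifit2, were each lost in limma without population C replicate 1 (adjusted p = 0.13, 0.116 and 0.13), C replicate 3 (0.0517, 0.087 and 0.119), D replicate 2 (0.114, 0.105 and 0.174) or mouse 3 (0.342, 0.14 and 0.493), and with only C and D (0.109, 0.0997 and 0.153). Ifit2 was also lost without any 1 of the other libraries except D replicate 1 (0.0619 to 0.132). Oas3 was also lost without A replicate 1 (0.053), A replicate 3 (0.0529), B replicate 3 (0.0527) or D replicate 3 (0.0862), and Oasl2 without B replicate 2 (0.0503) or D replicate 1 (0.0688). The called Ly6e peak was lost with only C and D (0.0745), without mouse 1 (0.0671), without mouse 3 (0.0586) and with thinned libraries (0.117). The lists of naive and quiescence (adjusted p = 0.12), AP-1, NFAT and NF-kB (0.239), T cell identity (0.0953), B cell (0.363), myeloid (0.309) and CD8 T and NK genes (0.246) were not called by camera in limma.

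The step from A to B raises the reporter among Ly6C positive cells. No single peak passed the limma threshold. At Cd5, a receptor whose level follows T cell receptor signal strength, an intron 1 peak stood at 1.46 ± 0.0679 rppm in A and 4.12 ± 0.496 in B (log2 1.05, limma adjusted p = 0.287, and 0.0664 with the mouse block). At Ifng the values were 1.2 ± 0.156 and 3.19 ± 0.247 rppm (log2 0.93, limma adjusted p = 0.287). Near Il2ra, the high-affinity IL-2 receptor chain, they were 37.1 ± 0.474 and 27.1 ± 2.77 rppm (log2 -0.44, limma adjusted p = 1).

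limma called 0 peaks between B and A, with 1218 at an unadjusted p below 0.05, while edgeR called 0 and DESeq2 8. With the mouse block limma called 27, of which 21 were higher. Camera called negative regulators higher (limma adjusted p = 0.000416, and adjusted p = 0.0525 with an estimated correlation). It also called regulatory T cell (adjusted p = 0.0139), effector (0.0273), receptor-induced (0.0451), follicular helper (0.0462) and thymocyte genes (0.0462) higher. Those calls were lost with an estimated correlation (adjusted p = 0.194, 0.209, 0.209, 0.209 and 0.267 in that order), and with the mouse block receptor-induced (adjusted p = 0.0543) and follicular helper genes (adjusted p = 0.0556) were not called. On simulated data at this size, 53% of 2-fold and 15% of 1.5-fold changes were recovered.

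The step from B to C exchanges Ly6C positive for negative cells at intermediate reporter. The 1 called peak lay between genes on chromosome 12 (25600650 to 25601483), 472 kb from Gm17746, a non-coding gene, and rose from 0.872 ± 0.185 to 4.28 ± 0.322 rppm (log2 1.5, SE 0.17, limma adjusted p = 0.0199). It is named because the count is 1, after its values were seen. Its call was lost without any 1 library of B or C (limma adjusted p = 0.115 to 0.251, log2 1.42 to 1.56) and without population D replicate 3 (adjusted p = 0.0519). It was also lost at a pseudocount of 5, with quantile normalization, with thinned libraries and without mouse 3, where limma called no peak in this step. The Tnfrsf4 promoter stood at 6.16 ± 0.3 and 12.6 ± 0.669 rppm (limma adjusted p = 0.07, and 0.0119 with the mouse block), the Ctla4 peak at 3.37 ± 0.417 and 6.49 ± 0.202 rppm (0.162 and 0.0303), and the Ikzf2 peak at 0.378 ± 0.354 and 2 ± 0.311 rppm (0.172 and 0.0156). edgeR called these 3 (adjusted p = 0.00745, 0.035 and 0.0457), as did DESeq2 (0.000172, 0.0212 and 0.0016), and without population D replicate 1 limma called Tnfrsf4 (adjusted p = 0.0262) and Ikzf2 (0.0287). At the Ly6c1 peak the values were 16.1 ± 0.882 and 11 ± 1.03 rppm (log2 -0.51, limma adjusted p = 0.325, and 0.0737 with the block).

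limma called 1 peak between C and B, with 1820 at an unadjusted p below 0.05, while edgeR called 71 and DESeq2 86. With the mouse block limma called 88, of which 71 were higher and 17 lower. The count was 26 without population D replicate 1, 0 without any 1 library of B or C or without population D replicate 3, 0 without mouse 3, and 0 at a pseudocount of 5. Camera called follicular helper (limma adjusted p = 2.53e-07, and adjusted p = 0.0188 with an estimated correlation) and regulatory T cell genes (7.27e-05, and adjusted p = 0.0429) higher. It called Ly6 (limma adjusted p = 2.53e-07) and CD8 T and NK genes (0.0215) lower, both lost with an estimated correlation (adjusted p = 0.177 and adjusted p = 0.242). Adjusted over the list alone, 6 follicular helper, 4 regulatory T cell, 3 negative regulator and 2 receptor-induced peaks were higher and 2 Ly6 peaks lower. Follicular helper genes were not called with the mouse block and an estimated correlation (adjusted p = 0.0825), nor on promoter peaks alone (camera in limma, adjusted p = 0.0865).

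C against A and D against B, like D against A, differ in both markers. limma called 384 peaks between C and A (342 higher, 42 lower), and 1590 with the mouse block. Their number was 4 without population A replicate 1, 10 without A replicate 3, 80 without C replicate 3, 112 without C replicate 2, 180 without C replicate 1, 209 without B replicate 3, 239 without B replicate 2, 242 without D replicate 3, 775 without D replicate 1 and 0 without mouse 3. Between D and B 5006 peaks were called (3260 higher, 1746 lower), 8361 with the mouse block and 1198 without mouse 3. Across the 4 populations 4385 peaks differed, 7960 with the block and 751 without mouse 3.

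Called peaks mostly followed the order of the populations. Of the 3957 peaks higher in D than in A, 2902 (73.3%) had means rising from A through B and C to D, with median log2 steps of 0.23, 0.20 and 0.60. Of the 1701 lower peaks, 1166 (68.5%) fell in that order, with medians of -0.11, -0.15 and -0.44. The end points of these sets were chosen by the D against A test. Across 45508 peaks, which are not independent replicates, the B minus A and D minus C changes correlated at Pearson r = 0.28 and Spearman rho = 0.19, at r = 0.26 with the mouse block and at r = 0.15 with libraries thinned to equal reads.

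The D minus C step differed from the B minus A step at 287 peaks by limma. Taken with its sign, the D minus C change was the higher one at 277 and the lower one at 10. With the mouse block 985 peaks differed, and it was the higher one at 614 and the lower one at 371. A lower change can be a larger fall, as at Atn1, with log2 -0.8 from C to D and -0.06 from A to B. The peak 65.5 kb from Ppp2r5c, a phosphatase subunit gene (chromosome 12, 110381120 to 110382306), changed by log2 2.59 from C to D and 0.08 from A to B. Its means were 0.105 rppm in A and 0.167 in B, where 1 read in A is worth 0.1007 to 0.1088 rppm. The pseudocount thus compresses the change from A to B, and edgeR did not call the difference (adjusted p = 0.63). The count depends on single libraries: it was 62 without population A replicate 1, 89 without A replicate 3, 156 without B replicate 3, 175 without B replicate 2, 184 without C replicate 2, 185 without D replicate 3 and 191 without B replicate 1. It was 77 at a pseudocount of 0.25, 0 among peaks of at least 5 rppm, 0 without mouse 3 and 20 by edgeR. The steps are not the same interval of reporter level.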

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

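The tests of explanations, the thinned libraries and the omission of mouse 3 were chosen after the result was seen, and the test of the difference between the steps, the pseudocounts, edgeR, DESeq2, the mouse block and the omission of single libraries were fixed before. At 287 peaks the change from C to D differed from the change from A to B by the limma test of that difference, and at 277 of them the change from C to D was the higher one. With the mouse as a block it was the higher one at 614 of 985 peaks and the lower one at 371. The peaks with the smallest p and a gene symbol are given here, 5 with a difference above 0 and 3 with one below. Each of these 3 fell from C to D, by more than it changed from A to B. Near Ppp2r5c, a phosphatase subunit gene, the difference was log2 2.51 (SE 0.22, limma adjusted p = 0.00142), with means of 0.105, 0.167, 1.62 and 14.7 rppm from A to D. At Scyl2 it was 2.85 (SE 0.27, limma adjusted p = 0.0015), with 0.419, 0.605, 0.567 and 11.6 rppm. At Cx3cr1, a chemokine receptor, it was 2.11 (limma adjusted p = 0.00213), with 0.314, 0.229, 0.338 and 4.42 rppm, at C1ql3 2.2 (limma adjusted p = 0.00213) and at Arhgap20os 2.08 (limma adjusted p = 0.00218). At Atn1 it was -0.75 (limma adjusted p = 0.0253), with 45.2, 43.3, 40.2 and 22.6 rppm, at Hspa8, a chaperone gene, -0.70 (limma adjusted p = 0.0264) and at the promoter of Irgc1 -1.12 (limma adjusted p = 0.0264). By edgeR the same differences had adjusted p of 0.63 at Ppp2r5c, 0.0899 at Scyl2, 0.0822 at Cx3cr1, 0.174 at C1ql3, 0.279 at Arhgap20os, 0.0833 at Atn1 and Irgc1 and 0.104 at Hspa8, so none of the 8 was called there, and with thinned libraries none was by limma (adjusted p from 0.0577 at Scyl2 to 0.417 at Irgc1). DESeq2 called Scyl2 (adjusted p = 0.00497), Cx3cr1 (0.0119) and Atn1 (0.0209), and not the other 5 (0.0582 to 0.827). Without mouse 3 limma called 0 such peaks, and the 8 had adjusted p from 0.722 to 1 at differences from -1.08 to 3.07. The limma calls at Atn1, Hspa8 and Irgc1 were also lost at a pseudocount of 0.25 (adjusted p from 0.0549 to 0.0575) and without any 1 of both A libraries, the 3 B libraries, C replicates 2 and 3 and D replicate 2 (0.0561 to 0.21), at differences from -0.65 to -1.28. Those at Hspa8 and Irgc1 were lost without C replicate 1 (0.0502 and 0.0553), and those at Atn1 and Hspa8 without D replicate 3 (0.068 and 0.0597). Without population A replicate 1 the count fell to 62, and without A replicate 3, B replicate 3, B replicate 2, C replicate 2, D replicate 3 and B replicate 1 it was 89, 156, 175, 184, 185 and 191.

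The number of such peaks rests in part on the scale. It rose from 77 at a pseudocount of 0.25 to 287 at 1 and 544 at 5, so compression of low values by the pseudocount may account for much of the count. That the C to D step was the larger one is a separate matter. Compression does not produce the wider spread of edgeR changes at 35075 peaks of at least 5 rppm (SD 0.273 for D minus C and 0.168 for B minus A, a ratio of 1.63), fewer A libraries do not explain 1796 calls with a C library left out, and unequal depth does not explain 945 calls after thinning, where B against A had 0 by limma. A larger step in receptor signal from C to D stays open and was not tested, since the reporter level of each gate is not in the data.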

How the results depend on the processing

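The thinned libraries and the omission of mouse 1 or mouse 3 were chosen after seeing the data, and all other settings here were fixed before. For 134 called changes at named peaks under 26 settings, 3122 values kept the call, 289 lost it and 0 turned direction. For 13 uncalled ones 314 values stayed uncalled and 20 passed the threshold, all in the lower steps and mostly with the mouse block, edgeR or DESeq2. No value exists for 69 of these changes among peaks of at least 5 rppm and for the 8 of the difference with only the populations compared. No peak called in D against A, D against C or D against B was called the other way under any setting. The median log2 change of all peaks, over all settings and pairs of populations, stayed between -0.059 and 0.028. Motif shares and the GC correction were not run for want of a genome sequence. For the values below the cause was not tested, except that the filter and thinning leave fewer peaks or reads, and the restriction to the populations compared and the omission of a mouse leave fewer libraries.

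With the mouse as a block the counts were D against A 9668, B against A 27, C against B 88, D against C 5166, C against A 1590, D against B 8361, the difference of the steps 985 and any population 7960. With the block and the width correction they were 9737, 21, 111, 5383, 1616, 8378, 1053 and 8172. Among peaks of at least 5 rppm, D against A had 3078, C against B 0, D against C 1144, C against A 158, D against B 2682, the difference 0 and any population 2209. With thinned libraries these were 2742, 0, 945, 22, 2236, 0 and 2086 in the order D against A, C against B, D against C, C against A, D against B, difference and any population, and the correlation was 0.15. With only the populations compared, D against A had 3763, D against C 1426 and C against A 234. At a pseudocount of 0.25, C against B had 3, the difference 77 and the correlation was 0.32, and at 5 C against B had 0, C against A 105, the difference 544 and the correlation was 0.23. Quantile normalization gave C against B 0, C against A 93, the difference 507 and a correlation of 0.19. Robust moderation gave C against B 2. edgeR gave C against B 71, C against A 631, the difference 20 and a correlation of 0.36. DESeq2 gave B against A 8, C against B 86, the difference 86 and a correlation of 0.37. Without mouse 1, C against A had 255 and the correlation was 0.21. Without mouse 3, D against A had 1024, C against B 0, D against C 404, C against A 0, D against B 1198, the difference 0, any population 751 and the correlation was 0.2, and 59 named changes lost their call. Beside the counts of 0 in C against B, limma gave 1749 (pseudocount 5), 982 (filter), 1631 (quantile), 1816 (thinned) and 723 (without mouse 3) at an unadjusted p below 0.05, and beside those of the difference 2255 (filter), 2740 (thinned) and 1398 (without mouse 3), and in C against A 1205 (without mouse 3).

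Lists called fell from 8 to 3 in D against A, from 6 to 0 in B against A, from 4 to 2 in C against B and from 8 to 3 in D against C with an estimated correlation, and fry called 1 in B against A and 2 in C against B. In D against A fry kept each list that camera had called (highest fry adjusted p = 0.0178, for interferon). In D against C it kept each but Ly6 (fry adjusted p = 0.0712). Fry asks whether the peaks of a list shift at all, and camera whether they shift more than the other peaks. The calls kept by fry therefore do not show that a list stands out from the other peaks. On promoter peaks alone camera in limma lost interferon in D against A (adjusted p = 0.0731) and receptor-induced genes in B against A (0.192). It also lost follicular helper genes in C against B (0.0865) and effector genes in D against C (0.0994). Directions turned for lists that camera in limma had not called on all peaks. In D against A these were AP-1, NFAT and NF-kB on promoter peaks (adjusted p = 0.0347, called lower) and myeloid by fry (0.788) and on promoter peaks (0.33). In B against A they were interferon (0.945) and B cell (0.775) by fry, and interferon (0.702), Ly6 (0.784), AP-1 (0.682) and B cell (0.337) on promoter peaks. In D against C they were AP-1 (0.214) and myeloid (0.689) on promoter peaks.

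Leaving out 1 library gave 2930 (A replicate 3) to 6042 (D replicate 1) for D against A, 0 to 0 for B against A, 0 to 26 (D replicate 1) for C against B, 1796 (C replicate 2) to 2897 for D against C, 4 (A replicate 1) to 775 (D replicate 1) for C against A, 3353 to 5381 for D against B, 62 (A replicate 1) to 341 for the difference, 3204 to 4481 for any population and 0.22 to 0.3 for the correlation. Where 1 library of A was left out, alone or with the rest of mouse 1 or mouse 3, the other was assumed to vary like the remaining groups. At 10 rppm a peak rested on 26 reads in D replicate 1 and 369 in D replicate 3, so small differences at low peaks were not detectable in the shallow libraries.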

Other observations

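The tests of genes, of held-out mice, of shared direction and of explanations, and the thinned libraries and the omission of mice, were chosen after the results were seen, and the mouse block, the omission of single libraries and the splits of libraries were fixed before. Several genes had more changed peaks in D against A than their number of peaks would give (hypergeometric test over 14922 genes, with neighbouring peaks not independent). For higher peaks 46 genes passed, among them Nt5e, the ectoenzyme CD73 found on anergic cells (7 of 7 peaks), F13a1 (7 of 7), Ndrg1 (9 of 13), Ikzf2 (8 of 11), Tnfrsf9 (6 of 7), Jak2, a cytokine receptor kinase (6 of 9), Hif1a (5 of 7), Bcl2l11, which encodes the death-promoting protein Bim (8 of 19), and Gfi1, a repressor (6 of 11). For lower peaks 19 genes passed, among them Pik3r5, a PI3 kinase subunit (9 of 11), Gramd3 (10 of 23), Il7r, the survival cytokine receptor of naive cells (8 of 19), and Ly6e (5 of 12). On chromosome 12, in the stretch from the end of Id2, an inhibitor of E proteins (25096092), to the start of Sox11 (27334268), 23 of 45 peaks (51.1%) were higher and 0 lower, against 8.7% of all peaks that were higher. They include 12 of the 15 peaks nearest to Gm29687 and 11 of the 22 nearest to Gm17746, non-coding genes, and the 1 peak called from B to C. On chromosome 19, from Cd5 to the end of Cd6 (10718107 to 10830062), 21 of 28 peaks (75%) were higher and 0 lower.

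With the mouse as a block, the lower steps had called peaks too. From A to B 27 were called, 21 higher and 6 lower. They include a peak in intron 1 of Cd5 (chromosome 19, 10731735 to 10732468), at 5.42 ± 1.11 rppm (SD, n = 2) in A and 13.3 ± 3.59 (n = 3) in B (log2 1.33, limma adjusted p = 0.0058), and 1 near Nr4a1 (31.2 to 45 rppm, limma adjusted p = 0.0334). Without the block limma called neither (adjusted p = 0.826 and 1). The Nr4a1 peak was not called with the block and the width correction (limma adjusted p = 0.0616), by edgeR (1) or by DESeq2 (1), and the Cd5 peak was called with that correction (limma adjusted p = 0.00266) and by DESeq2 (0.0439) but not by edgeR (0.7). From B to C 88 were called, 71 higher and 17 lower. Without the block, D against A, which shares the A libraries with the step from A to B, was called in the same direction at 21 of 21 higher and 0 of 6 lower peaks of that step, and at 71 of 71 and 13 of 17 of the step from B to C. Of all peaks, 8.7% were called higher and 3.74% lower in D against A. The shared A libraries by themselves favour agreement with the step from A to B. The peaks called from B to C include Tnfrsf4 (limma adjusted p = 0.0119), Ikzf2 (0.0156), Ctla4 (0.0303) and Icos (0.0384). Without mouse 1 limma called 5835 peaks in D against A, and without mouse 3 1024. In mouse 1, 94.4% of 4180 peaks called higher and 92.5% of 1655 called lower without that mouse had the same direction, and in mouse 3 100% of 937 and 100% of 87.

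A hypothesis is that accessibility is graded, so that peaks changed at one step move the same way at a step measured in other libraries. Of peaks called higher from C to D, 81.7% were also higher from A to B, against 63% to 70.4% (median 66.6%) in 1000 sets matched on peak level, and for lower peaks 59.7% were also lower, against 40.7% to 51.8%. Of peaks called higher in D against A, 84.9% were higher from B to C, against 45.3% to 50.4%, and of lower ones 85.1% were lower, against 50% to 57.4%. In each case 0 of the 1000 sets were as high, so a trend with peak level alone does not account for it. The sets draw peaks as if they were independent, so their range does not measure spread between libraries or mice. They were not drawn with the mouse block. The steps use other libraries but share mice, and A has no library of mouse 2. For the steps from A to B and from C to D, each within 1 Ly6C class, a graded response to receptor signal may account for it, which was not tested. Within these classes the Ly6c1 peak also went down, from 20.3 rppm in A to 16.1 in B (not called) and from 11 in C to 5.46 in D. A difference tied to Ly6C, or a rising share of other cells, therefore cannot be told from such a response in these steps. B and C are both reporter intermediate and differ in Ly6C, as D and A also do. The comparison with the step from B to C therefore cannot tell such a response from a difference tied to Ly6C. With the mouse block, 46.6% of peaks called lower from C to D were lower from A to B, the same share as of all peaks (46.6%), so for lower peaks the first of these comparisons does not hold there.

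The shallow D replicate 1 does not account for the number of peaks that differed between D and A, since 6042 were called without it and 5658 with it. In libraries thinned to equal reads 45.9% of the 5658 kept their call and direction, so unequal depth does not account for those. For the other calls thinning cannot tell, since it also leaves fewer reads. For the lower peaks, less than 25% of other cells in D could not take the ratio of D to A below 0.75. In mouse 1 the peaks called lower without that mouse had a median ratio of 0.648 (95% bootstrap interval over peaks 0.631 to 0.656, quartiles 0.486 to 0.797). In mouse 3 those called lower without it had 0.445 (0.419 to 0.484). Both medians argue against such a share for these peaks as a set, though not for each peak. Each rests on 1 library of D and 1 of A, so the intervals do not measure spread between mice. The calling without either mouse had 1 library of A. For the higher peaks such a share of other cells stays open, since 99.6% of the rises (median 4.99 rppm) could come from 25% of cells at an accessibility that other peaks have in A. Regulatory T cells, which the Foxp3 reporter gate should remove, are a candidate source: 27 peaks of their list were higher and 4 lower of 92, 6 of its 18 genes stand in another list, and the peak of Foxp3 itself stood at 3.74 rppm in A and 5 in D (limma adjusted p = 0.387). A response to receptor signal was not tested apart from the sort itself.

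Splitting the 6 libraries of a pair of populations in the 10 possible ways gave as many calls in 1 split, the real one, for D against C (2730, highest other 0), C against B (1, highest other 0) and D against B (5006, highest other 0), and 10 splits are too few for a share under 0.05. The first principal component held 46.2% of the variance and the second 22.4%, on which the 4 libraries of mouse 1 lay at 12.6 to 44.3 and the other 7 below 0. A pair of adjacent peaks on chromosome 1 (24611585 to 24616135), where the genome holds a copy of mitochondrial DNA, had 1066 rppm in population B replicate 1 and 4332 to 8186 rppm in the other libraries.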
